A study of Mus musculus with 14 samples.

How the data were processed

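Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against the histone variant H2A.Z was carried out on mouse small intestinal epithelium at 4 stages, per the labels. The stages were epithelial cells of E12.5 and E14.5 embryos, adult Lgr5+ intestinal stem cells (ISC) and adult enterocytes, with 2 H2A.Z libraries each. The labels describe cells sorted for the epithelial marker EpCAM and against the markers CD31 and CD45 in embryos, and adult cells from male mice. The series text calls the 2 libraries of a stage biological duplicates. Neither text says whether these came from separate animals or pools, so the p-values of tests between libraries measure only the spread between these libraries. Those of Fisher's tests and of clustering are taken over regions and measure no spread between libraries.

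The deposited lists hold 1 set of peaks per H2A.Z library, called against input DNA and not pooled. Peaks were called with MACS 2.1.0.20140616 in broad mode at a q cutoff of 0.05 and a model fold range of 10 to 30, per the file headers. The submitters' processing notes also name bcl2fastq 1.8.4, Bowtie 1.1.2, SAMtools 1.2 and the genome build mm9. Each embryonic library had its own input, whereas the 2 ISC libraries shared 1 input and the 2 enterocyte libraries shared another, per the file headers. An input that differs in quality would therefore act on both adult libraries of a stage together. The 6 input samples entered only through this calling.

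The pileup of each peak is a coverage signal, and it was written by MACS per the file headers. The −log10 p and −log10 q of each peak, likewise deposited by the authors, measure the evidence against the input. The fold enrichment of each peak is a ratio to the local background as the authors' caller computed it. These values belong to single peaks of 1 list. They were used to rank, filter or describe peaks within a list and never as a change between libraries. The fragment size that MACS estimated per library sets how far each read is extended and the smallest width of a peak. It was 67 bp in enterocyte replicate 1 and 71 bp in E14.5 replicate 2, close to the read (tag) length of 68 bp, and 191 to 247 bp in the other libraries. The labels give fragments of 350 to 700 bp for every sample, above all of these estimates. A short fragment size below means a small estimate, and does not show that the DNA of these libraries was shorter.

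All peaks were merged into union regions wherever peaks of any library overlapped by 1 bp or touched. A library had a region if at least 1 of its peaks lay in it. A region counted as present in only 1 of 2 stages when both libraries of that stage and neither library of the other had it. For embryonic against adult, it had to be in all 4 libraries of a side and in none of the other. The counts were set beside those of the other splits of the same libraries, which number 2 for a pair of stages and leave no p below 0.333, and 35 in all for embryonic against adult, of which 3 keep the libraries of every stage together. The similarity of libraries was the Jaccard index, the number of regions shared over the number in either library. Its mean within stages was tested by an exact one-sided permutation test over all 105 ways to form 4 pairs. Width quartiles and the shares of peaks on the X and Y chromosomes were compared between the adult and embryonic libraries by exact two-sided permutation tests, with Benjamini-Hochberg adjustment over 5 measures. Shares of regions have 95% Wilson intervals, which cover counting error only, and neighbouring regions are not independent.

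Peak lists differed in length, so the counts of stage-dependent regions, the Jaccard indices, peak widths, the X and Y shares and Fisher's tests of X-linked regions were repeated with the 6136 strongest peaks by p of every library. The calls of ISC regions in enterocytes and the clustering of regions were not. Lists of equal length bring the counts of both directions towards balance by construction. A region listed on 1 side alone in this way can hold a weaker peak of the other side, so the number with a peak in at least 1 full list of the other side was counted as well. Other alternatives fixed before the data were examined were coverage of at least 50% of a region, a −log10 q of at least 10, merging within 500 bp, autosomes alone, a replicate block and leaving out each library. Several comparisons were chosen after the data had been seen. These were 100 randomised presence tables that keep the number of libraries per region and of regions per library, a −log10 q of at least 2, and lists without both libraries of short fragment size. Equal numbers of peaks among the compared libraries alone, that look into the full lists, E12.5 against ISC, the counts of X-linked regions, the fate of ISC regions in enterocytes and the clustering of regions were also added then. Fisher's exact tests of X-linked regions were two-sided and adjusted over 8 tests.

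Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The counting was tested on simulated data with 45028 regions for each of the 4 comparisons. Of 200 regions planted per direction, 100% were recovered in each comparison and 0 took the wrong direction. Planted regions met the counting rule in every library by construction, so this checks the code alone. In 200 simulations without a stage effect, 6% gave a concordance p at or under 0.05. The simulated libraries were of like length, whereas the real lists were not.

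Positions are those of the deposited files in mm9. The gene table used here is on GRCm38, and its coordinates were not used: the peaks on chromosome 1 reach 197068299, beyond its last gene end at 195291439. The tests of marker gene promoters and the shares of peaks in promoters, genes and intergenic sequence, both planned, were therefore not run. No annotation is given for any region. The rule fixed beforehand for this case names, per comparison and direction, the 5 regions with the highest authors' fold in the list of the first replicate.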

Results

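H2A.Z, a variant of the core histone H2A found at many promoters and enhancers, was mapped in the mouse small intestinal epithelium before birth and in the adult. The stages were E12.5 and E14.5 epithelium, adult Lgr5+ ISC, the dividing stem cells of the crypt base, and adult enterocytes, the absorptive cells of the villus. The number of H2A.Z peaks was highest in ISC, with a mean of 29528 ± 3681 (SD, n = 2), followed by E12.5 with 24118 ± 2745 (SD, n = 2). Enterocytes had 17369.5 ± 4403 peaks (SD, n = 2) and E14.5 epithelium 11712 ± 7886 (SD, n = 2). The covered sequence was 30.2 ± 2.50 Mb in ISC, 20.9 ± 3.63 Mb at E12.5, 13.2 ± 8.82 Mb in enterocytes and 7.87 ± 8.61 Mb at E14.5 (SD, n = 2 each).

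Sequencing depth lay between 27835048 tags in E14.5 replicate 2 and 41274126 in enterocyte replicate 2, and the inputs held 31049250 to 34328629. The replicates of E14.5 and of enterocytes were unlike each other. E14.5 replicate 1 had 17288 peaks of median width 731 bp, and replicate 2 had 6136 of 238 bp. Enterocyte replicate 1 had 14256 peaks of median width 388 bp, and replicate 2 had 20483 of 835 bp. The libraries with narrow peaks were those with a fragment size of 71 and 67 bp. In the other libraries the median width was 731 to 921 bp.

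**Figure D1:**
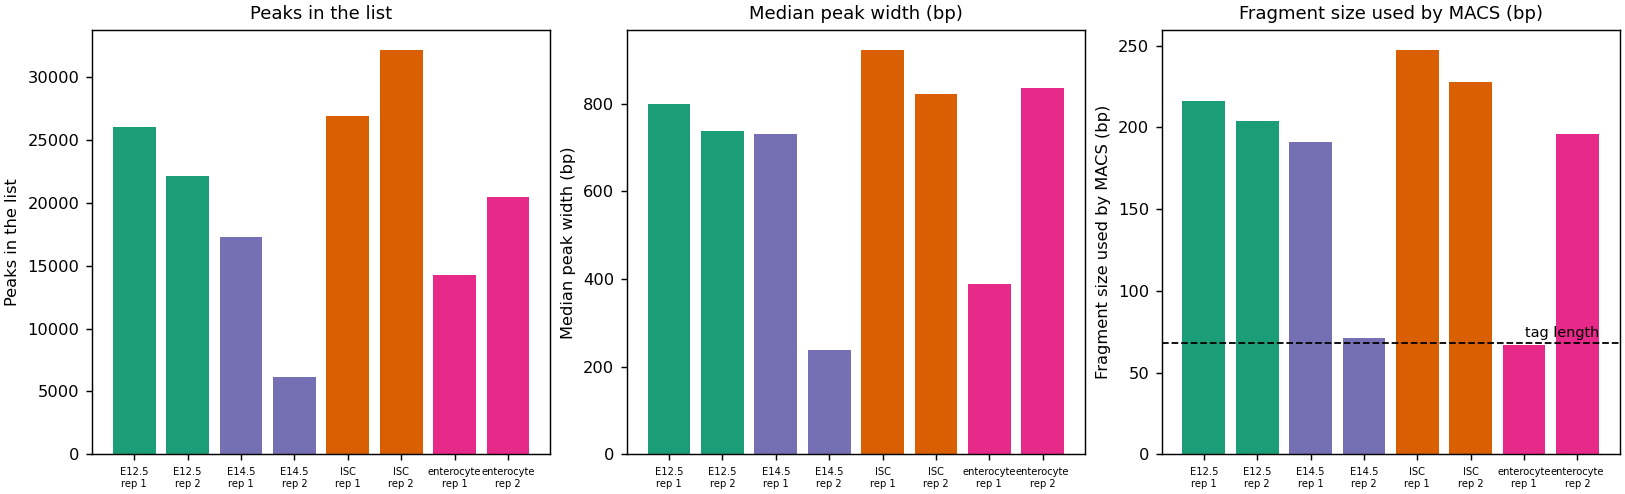
Bars give, for each of the 8 H2A.Z libraries, the number of peaks, the median peak width in bp and the fragment size in bp used for peak calling, coloured by stage. E14.5 replicate 2 and enterocyte replicate 1 have the shortest lists, 6136 and 14256 peaks, and fragment sizes of 71 and 67 bp next to the dashed line at the tag length of 68 bp.

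The peaks of all libraries formed 45028 regions. Of these, 3999 (8.88%) carried H2A.Z in all 8 libraries and 13738 (30.5%) in a single library. The regions of all 8 libraries were broad, with a median of 1750 bp, and those of a single library were narrow, with a median of 357 bp. Joining peaks of more libraries widens a region by construction. In the regions of all 8, the median covered by a single library was 289 bp in E14.5 replicate 2 and up to 1567 bp, in ISC replicate 2. Both libraries of a stage shared 24195 regions in ISC, 19381 at E12.5, 11436 in enterocytes and 5292 at E14.5.

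On average, libraries of a stage shared more H2A.Z regions than libraries of different stages. The Jaccard index was 0.700 between the ISC libraries, 0.683 at E12.5, 0.561 in enterocytes and 0.307 at E14.5. Its mean within stages was 0.563, against 0.416 between stages, the highest of all the ways to form 4 pairs of libraries (exact one-sided permutation p = 0.00952). The highest of the other pairings reached 0.547. With 6136 peaks per library the means were 0.568 and 0.427 (exact one-sided permutation p = 0.00952). The mean did not hold for each library. E14.5 replicate 1 had a higher index with all 6 libraries of the other stages, 0.444 to 0.623, than with its own replicate, and with 6136 peaks per library it did so with the E12.5 and ISC libraries, 0.444 to 0.499 against 0.432. E14.5 replicate 2 had 0.311 with enterocyte replicate 1. Enterocyte replicate 2 had 0.605 with ISC replicate 1, against 0.561 with its own replicate, and 0.603 against 0.579 with equal numbers. The order of the stages depended on list length. In the full lists E12.5 and ISC were the most alike, with a mean of 0.486, and E14.5 and ISC the least, with 0.323. With equal numbers these were ISC and enterocytes, with 0.521, and E14.5 and enterocytes, with 0.345. The call ended without either E12.5 library (exact p = 0.0571), without ISC replicate 2 (exact p = 0.0952) and without enterocyte replicate 1 (exact p = 0.0667).

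**Figure D2:**
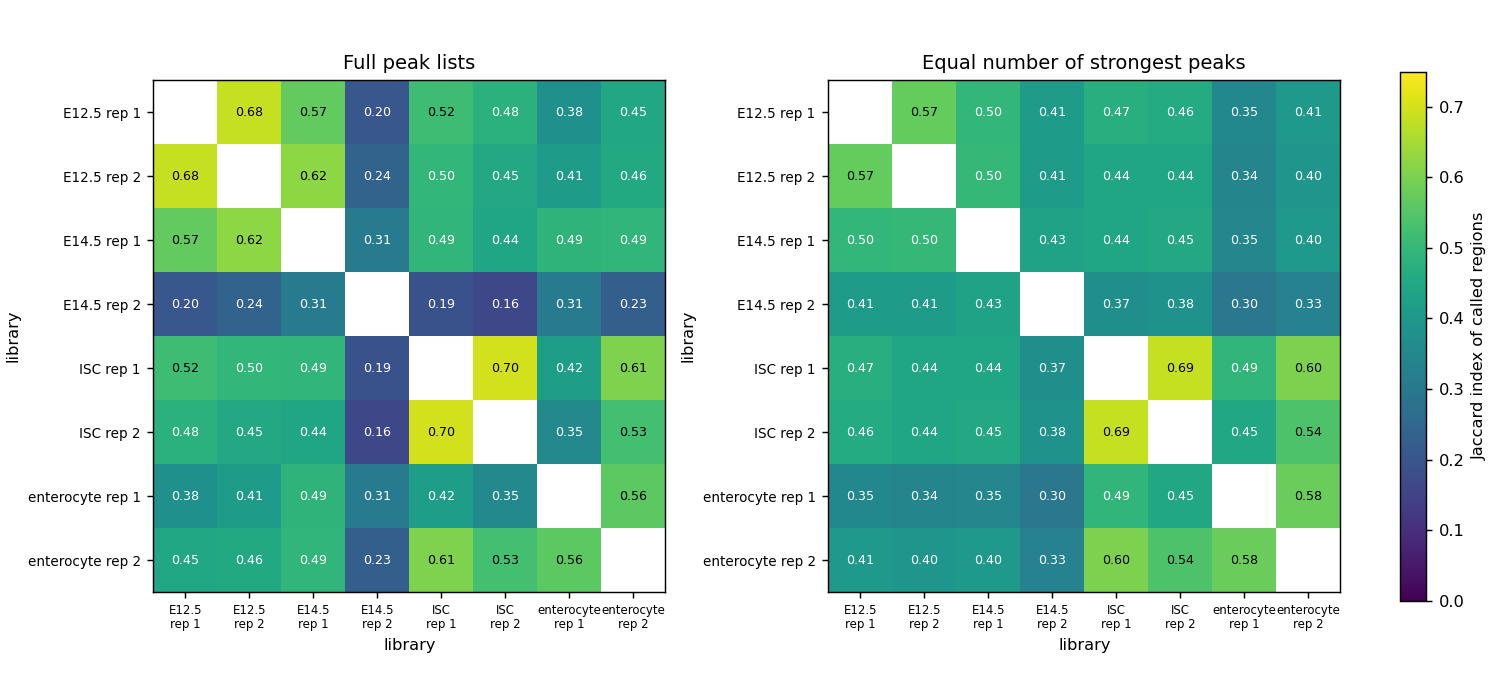
Each cell gives the Jaccard index of the regions called in 2 libraries, from the full lists on the left and from 6136 peaks per library on the right. The ISC pair, at 0.700 in the full lists, is the most alike, and E14.5 replicate 2 has low values with all libraries in the full lists.

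The first comparison followed the embryonic epithelium from E12.5 to E14.5. Peaks were called in both E12.5 and neither E14.5 library in 4693 regions, and the reverse in 57. All 4 libraries had peaks in 5159 regions. The E12.5 regions with the highest fold lay on chromosome 5 at 38698848 to 38699403 and on chromosome 3 at 88986998 to 88987778, with a fold of 6.49 and 6.30 in E12.5 replicate 1. The 5 named regions ranged from 5.97 to 6.49. Of the 57 E14.5 regions, 14 lay on the Y chromosome and 11 on X, and 10 of the latter between 120113770 and 123303417. The region with the highest fold was among these, on X at 121291720 to 121292398, with 4.02 in E14.5 replicate 1 and 7.42 in replicate 2. An autosomal one on chromosome 4 at 56234716 to 56235617 also had a peak in both ISC and both enterocyte libraries.

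The real split gave 4750 regions, against at most 891 in the other splits, which are too few for a p below 0.333. Randomised tables gave 3746 to 3953 regions in the direction of E12.5 and 6 to 22 in that of E14.5. Their share in the direction of E12.5 was 99.7%, against 98.8% in the data. List length and a difference between the stages therefore cannot be told apart as the source of the direction. With the 6136 strongest peaks of each library, 657 regions were listed in both E12.5 and neither E14.5 library and 428 the reverse, 60.6% (57.6 to 63.4) in the direction of E12.5. Lists of equal length bring such counts towards balance by construction, and they show a difference in rank, since 622 and 425 of these regions had a peak of the other stage in its full lists. The highest other split then gave 593 regions in all, against 1085. Without E14.5 replicate 2, the E14.5 count was 1166; without E14.5 replicate 1 it was 148, and without E12.5 replicate 1 it was 112. The E12.5 count was 10189 without E12.5 replicate 2 and 14151 without E14.5 replicate 1.

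The second comparison set the E14.5 epithelium against adult ISC. Both ISC and neither E14.5 library had a peak in 9833 regions, and 111 regions showed the opposite, beside 5066 shared regions. The ISC regions with the highest fold lay on chromosome 3 at 143861334 to 143862070 and on chromosome 11 at 62373760 to 62374808, with a fold of 6.41 and 6.23 in ISC replicate 1. The first of these also had a peak in both enterocyte libraries and in no embryonic library. Among the 111 E14.5 regions, that with the highest fold, 7.75 in E14.5 replicate 1, lay on chromosome 5 at 143664797 to 143665337. It had a peak in both enterocyte libraries as well, with a fold of 6.20 and 9.11, and in neither ISC library. The next 4, with a fold of 4.03 to 4.43, had peaks in the 4 embryonic libraries alone.

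The real split gave 9944 regions and the highest other split 692, with no p below 0.333 possible. Randomised tables gave 1 to 12 regions in the direction of E14.5 and 6649 to 6883 in that of ISC. Their share in the direction of E14.5 was 0.0868%, against 1.12% in the data. Here too, list length and a difference between the stages cannot be told apart as the source of the direction. Among the 6136 strongest peaks per library, 735 regions were listed on the side of E14.5 and 1118 on that of ISC, so that 39.7% (37.5 to 41.9) were in the direction of E14.5. Of these, 720 and 1013 had a peak of the other stage in its full lists. That total of 1853 stood against 341 in the highest other split. The E14.5 count was 1797 without E14.5 replicate 2, 212 without E14.5 replicate 1 and 201 without ISC replicate 2, and the ISC count was 19058 without E14.5 replicate 1 and 16765 without ISC replicate 1.

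The third comparison followed the differentiation of ISC into enterocytes. A peak was called in both libraries of 1 of these cell types and in neither of the other in 7087 regions. Of these, 6982 (98.5%) had it in ISC and the rest in enterocytes. All 4 libraries had peaks in 11145 regions. The ISC regions had a median width of 822 bp, against 1629 bp in the shared regions, and a median fold of 2.80 against 4.23 in ISC replicate 1. The shared regions join peaks of more libraries, which widens them by construction. The named ISC regions, with a fold of 5.57 to 6.28, all had peaks in at least 3 embryonic libraries. The highest lay on chromosome 2 at 93019714 to 93020946, with 6.28 in ISC replicate 1, followed by chromosome 12 at 109660792 to 109662046 with 5.78. In enterocytes, the region on chromosome 5 at 143664797 to 143665337 again had the highest fold. The next, on chromosome 9 at 114325771 to 114326430, had a fold of 4.96 and 3.83 and a peak in no other library.

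The highest other split gave 758 regions in all, with no p below 0.333 possible. Randomised tables gave 4894 to 5106 regions in the direction of ISC and 36 to 70 in that of enterocytes. Among the 6136 strongest peaks per library, 776 regions were listed on the side of ISC and 602 on that of enterocytes, 56.3% (53.7 to 58.9) in the direction of ISC, where randomised tables gave 55.0%. All but 19 and 1 of these had a peak of the other cell type in its full lists. The total of 1378 stood against 323 in the highest other split. With 14256 peaks from each of the 4 libraries the counts were 1677 and 727, 69.8% in the direction of ISC. The enterocyte count was 1637 without enterocyte replicate 1, 163 without enterocyte replicate 2, 208 without ISC replicate 1 and 188 without ISC replicate 2, and the ISC count was 13848 without ISC replicate 1 and 12979 without enterocyte replicate 2.

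**Figure D3:**
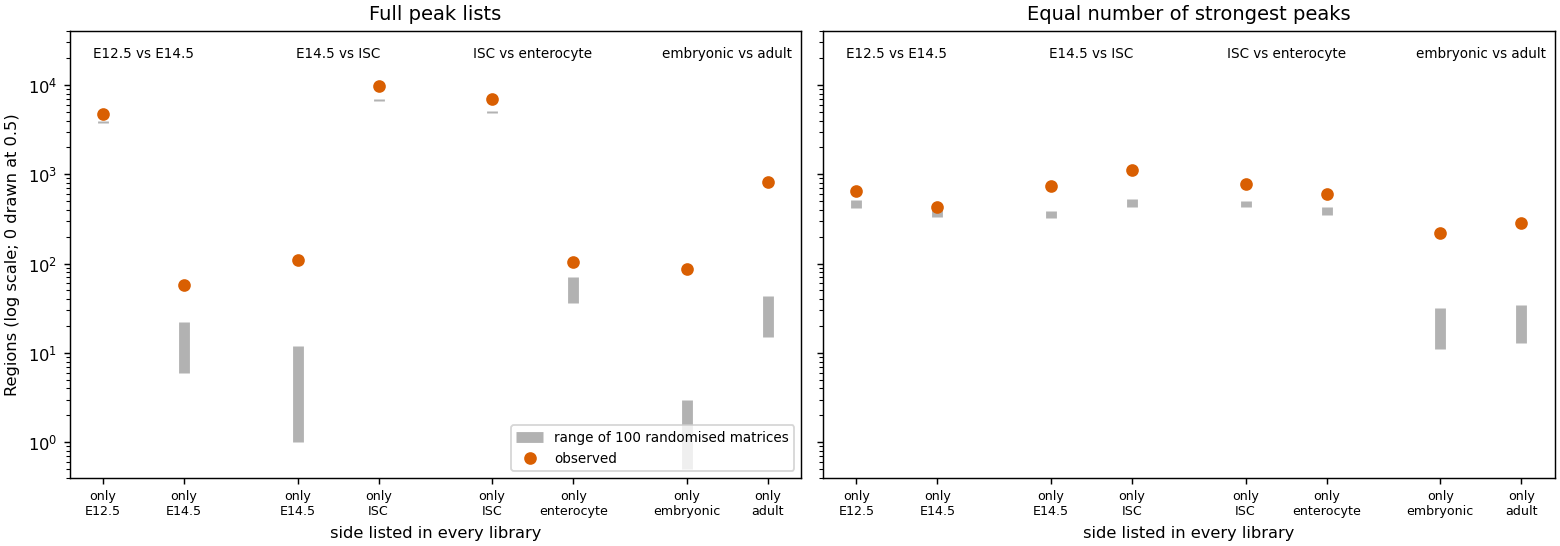
Points give the number of regions, on a log scale, listed in every library of the named side and none of the other, from full lists on the left and from 6136 peaks per library on the right. Grey bars span 100 randomised tables; the full lists are one-sided, with 6982 of 7087 regions in ISC when set against enterocytes, and the equal lists, whose length brings the counts towards balance, give 776 against 602.

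The adult cells were also compared with the embryonic epithelium as a whole. Peaks were called in all 4 adult and no embryonic library in 810 regions, and in all 4 embryonic and no adult library in 87. The adult regions had a median width of 1089.5 bp, against 814 bp in the embryonic ones. This is the width of joined peaks, which is at least that of the widest peak in a region. It therefore also depends on the peak widths of single lists, and the difference was not tested. The adult region with the highest fold was that on chromosome 3 at 143861334 to 143862070, with a fold of 6.41 and 5.47 in ISC and 3.84 and 4.23 in enterocytes. It was followed by chromosome 6 at 115742104 to 115743437, with 6.09 in ISC replicate 1 and 6.18 in enterocyte replicate 2. The highest embryonic region lay on chromosome 1 at 17716956 to 17718123, with 6.36 and 5.02 at E12.5 and 3.62 and 3.23 at E14.5. A stretch of chromosome 3 from 51810331 to 51893097, chosen after the data were seen, held 4 adult regions.

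The total of 897 regions was the largest of the 35 splits of the 8 libraries into 4 and 4, and the next gave 837. Of these splits, 32 broke up the libraries of a stage, and the 3 that kept them together gave 897, 837 and 31 regions. The split with 837 put E12.5 and ISC, the stages with the longest lists, against E14.5 and enterocytes. Randomised tables of the full lists gave 0 to 3 embryonic and 15 to 43 adult regions. Among the 6136 strongest peaks per library, 220 regions were listed on the embryonic and 283 on the adult side, 43.7% (39.5 to 48.1) in the embryonic direction, of which 214 and 278 had a peak of the other side in its full lists. The total of 503 stood against 64 in the next split. Randomised tables then gave 11 to 32 embryonic and 13 to 34 adult regions. The embryonic count was 845 without E14.5 replicate 2 and 147 without ISC replicate 2, and the adult count was 2773 without enterocyte replicate 1.

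**Figure D4:**
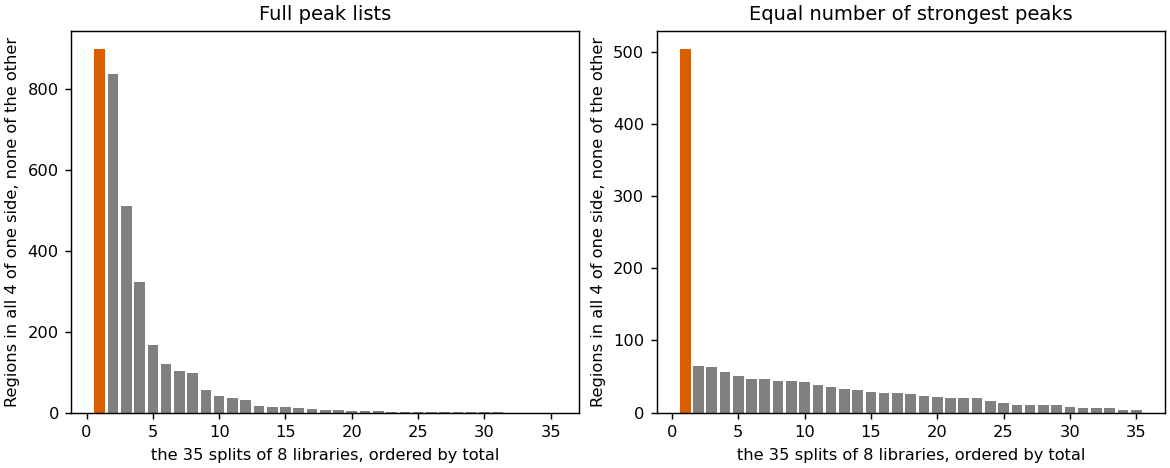
Bars give, for each of the 35 splits of 8 libraries into 4 and 4, the number of regions listed in every library of 1 side and none of the other. Full lists and lists of 6136 peaks per library are shown. The embryonic against adult split, in orange, gives 897 and 503 regions, and the next split 837 and 64.

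**Figure D5:**
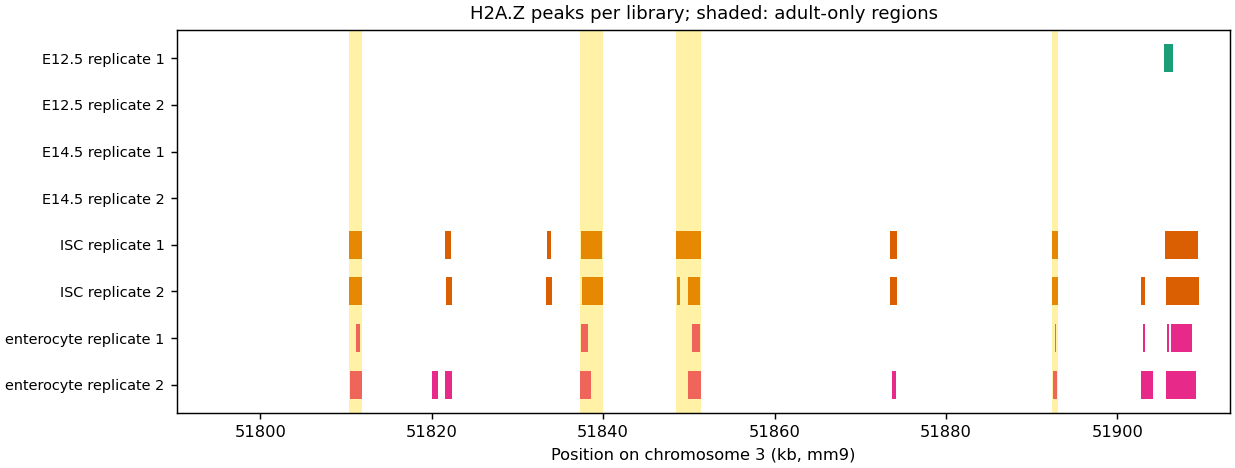
Bars mark the H2A.Z peaks of each library along chromosome 3 in kb (mm9), with the 4 adult regions between 51810331 and 51893097 shaded. The embryonic libraries have 0 peaks in that stretch, the ISC libraries 7 and 8, and the enterocyte libraries 4 and 7.

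No difference in the width or chromosomal location of peaks between adult and embryonic libraries passed the test. These tests exchanged libraries singly and ignored that each side held pairs of the same stage. The median peak width was 741 ± 239.6 bp in adult libraries and 626 ± 261 bp in embryonic ones (SD, n = 4 each; exact two-sided permutation p = 0.457, adjusted p = 0.543). The X chromosome held 1.81% ± 0.600 of adult and 2.11% ± 0.475 of embryonic peaks (SD, n = 4 each; exact permutation p = 0.457, adjusted p = 0.543). The width quartiles and the Y share gave the same adjusted exact p of 0.543, where the smallest unadjusted p possible was 0.0286. With the 6136 strongest peaks per library the median width was 309.6 bp higher in adult libraries (adjusted exact permutation p = 0.536), against 115 bp in the full lists. In the full lists without E14.5 replicate 2 it was 14.4 bp lower. The X share was 1.00% (0.852 to 1.18) in enterocyte replicate 1, 1.40% (1.14 to 1.73) in E14.5 replicate 2 and 1.69% (1.53 to 1.88) in enterocyte replicate 2, and 2.25 to 2.42% in the other libraries.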

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

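The tests of splits, depth, fragment size and list length and the look into the full lists in this part were chosen after their results had been seen, and that of peaks near the threshold was not. E14.5 replicate 2 stood apart from the other 3 embryonic libraries, by a gap test that finds about 1 in 20 groups by chance. Its median peak width was 238 bp, against 731 to 798 bp. Its X share was 1.40%, against 2.29 to 2.42%. Its Y share was 0.717%, against 0 to 0.0983%. These were 3 findings in 12 groups of libraries and measures tested. E14.5 replicate 2 also had 7 peaks on the mitochondrial chromosome, and the other libraries had 0. These peaks were kept among the union regions and were not analysed on their own.

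For embryonic against adult regions, 1 of the 35 splits gave a total as large as the real 897, the real split itself, and the highest other total was 837. With 6136 peaks per library it was again 1 of 35, with 503 regions against 64. That share of 0.0286 excludes chance only for libraries exchanged singly, since 32 of the splits broke up the libraries of a stage. The 3 splits that kept stages whole gave 897, 837 and 31 regions, and 503, 64 and 46 with equal numbers, and are too few for a share below 0.333. The full-list margin over the split that follows list length was small. Randomised tables, which keep list lengths, gave at most 3 embryonic and 43 adult regions in the full lists, against 87 and 810. They do not keep the libraries of a stage alike, so they do not decide between stages either.

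The short lists of E14.5 replicate 2 and enterocyte replicate 1 go with the one-sided counts of regions. Depth alone does not account for the list of enterocyte replicate 1, since 4 of the 6 libraries with longer lists had fewer tags. For E14.5 replicate 2, with 0 such libraries, depth cannot be told apart from other causes because it had the fewest tags. A fragment size set near the tag length stays open: the match of the smallest fragment sizes with the shortest lists, which has a chance of 0.0357, prompted that explanation and so does not test it. A weak precipitation also stays open.

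Between ISC and enterocytes, list length and a difference between the cell types cannot be told apart as the source of the direction. The share in ISC of 56.3% with equal numbers of peaks decides nothing, since lists of equal length bring it near balance, to 55.0% in randomised tables. Nor was it decided whether list length or peaks near the threshold account for the existence of such regions. With equal numbers these were 4.27 times those of the highest other split, with a median rank of 48.9% in ISC replicate 1, which met the bound of at least 25% set beforehand against peaks near the threshold, but 757 of the 776 ISC regions and 601 of the 602 enterocyte regions had a peak of the other cell type in its full lists. Both values therefore describe differences in rank, not presence, a reading adopted only after they had been seen and first counted against these explanations; the separate inputs of the stages also stay open.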

How the results depend on the processing

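The alternatives with a −log10 q of at least 2, without both libraries of short fragment size, and with equal numbers of peaks among the compared libraries were chosen after the data had been seen. Counts are given in the order of E14.5 alone against E12.5, E14.5 alone against ISC, enterocytes alone against ISC, embryonic alone and adult alone. They were 20, 20, 28, 12 and 214 where peaks had to cover 50% of a region, 30, 31, 57, 17 and 432 at a −log10 q of at least 2, and 1166, 1797, 1637, 845 and 2778 without both libraries of short fragment size. The last rise follows in part from fewer libraries that must have or lack a peak; the cause of the others was not tested. With 6136 peaks from all libraries, where a region listed on 1 side can have a weaker peak on the other, the counts were 657 and 428 for E12.5 and E14.5, 735 and 1118 for E14.5 and ISC, 776 and 602 for ISC and enterocytes, and 220 and 283 for embryonic and adult. With equal numbers among the compared libraries they were 660 and 427, 733 and 1118, and 1677 and 727. On autosomes alone, 32 regions were left to E14.5 against E12.5, since the others lay on X and Y. Merging within 500 bp kept all 11 results within 1.5 times or on their side of the threshold. A −log10 q of at least 10 left 0 peaks in enterocyte replicate 1 and 2 in E14.5 replicate 2, so it gave no value for the planned comparisons.

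Leaving out each library in turn gave 4764 to 14151 regions for E12.5 and 78 to 1166 for E14.5, 136 to 1797 for E14.5 and 9904 to 19058 for ISC, 7053 to 13848 for ISC and 163 to 1637 for enterocytes, and 87 to 845 embryonic and 813 to 2773 adult regions. Fewer libraries had to meet each condition, so these counts can only rise. The mean Jaccard index within stages was 0.517 to 0.648, with an exact p of up to 0.0952; under the other alternatives it was 0.345 to 0.692 and kept its call. With 6136 peaks per library the difference, adult minus embryonic, was 309.6 bp in median width, 261.4 bp in the lower quartile and −0.200 percentage points in the X share, and none of the 5 measures passed the test. Leaving out libraries, the difference in median width was −14.4 to 232.75 bp, that in the lower quartile −13.6 to 116.75 bp, that of the X share −0.539 to −0.0347 and that of the Y share −0.231 to 0.00764 percentage points. Without E14.5 replicate 2, 3 differences changed sign: the lower width quartile to −13.6 bp, the median width to −14.4 bp and the Y share to 0.00764 percentage points. These changes follow from its own values. It had a median width of 238 bp, against 731 to 798 bp in the other embryonic libraries, and a Y share of 0.717%, against 0 to 0.0983%. Why this library stood apart was not tested, and none of the differences had passed the test.

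Replicates with the same number did not deviate together, with correlations from −0.0878 to 0.087 between stages, so no pairing by number was seen. With 2 libraries per stage, this cannot exclude that those of the same number were processed together. With a replicate block, the mean Jaccard index was 0.563 with an exact p of 0.0417, and the block leaves each count of regions, such as 4693, as it was by construction.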

Other observations

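All tests and values in this part were chosen after the peak lists had been seen, and those of the ISC regions absent from embryos after the counts per stage were known; the bounds for the 2 tests of clustering were set before their results. E12.5 and ISC were compared because their 4 libraries had fragment sizes above 200 bp. Leaving the other stages aside, peaks were called in both E12.5 and neither ISC library in 2938 regions and the reverse in 6361. Another 15309 were shared, and the highest other split gave 581. At a −log10 q of at least 10 the counts were 135 and 2751. That cutoff left 5543 and 1719 peaks in the E12.5 libraries and 8350 and 7744 in the ISC libraries. List length and a difference between the stages therefore cannot be told apart in these counts. With the 22177 strongest peaks of each of the 4 libraries, which brings the counts towards balance by construction, they were 3212 and 3568. The E12.5 count was 6525 without E12.5 replicate 2 and 4751 without E12.5 replicate 1, and the ISC count was 12552 without ISC replicate 1. With the 6136 strongest peaks per library, 1040 and 1037 regions were listed on 1 side alone, and 1005 and 1020 of these had a peak of the other stage in its full lists.

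X-linked regions of ISC were called in enterocytes less often than autosomal ones. Of 578 X-linked regions present in both ISC libraries, enterocyte replicate 1 had 21.5% (18.3 to 24.98) and replicate 2 had 58.1% (54.1 to 62.1), against 47.0% and 71.2% of the autosomal regions. Within 10 strata of rank in the ISC lists, the odds ratio of autosomes over X was 7.14 (5.59 to 9.12) and 3.68 (2.98 to 4.56). At E12.5 it was 0.872 (0.691 to 1.101) and 1.06 (0.855 to 1.31), and at E14.5 it was 1.36 (1.12 to 1.66) and 2.75 (2.11 to 3.58). Both adult cell types came from males per the labels, and 18 Y regions were present in both ISC libraries, whereas the enterocyte libraries had 0 and 4 Y regions. X made up 3.41% of the regions in ISC and not in enterocytes and 1.08% of those shared (odds ratio 3.24, Fisher's exact adjusted p = 3.6e-26 across regions, which are not replicates). An excess of X was not particular to this comparison. X made up 2.66% of the regions at E12.5 and not at E14.5, against 0.989% of those shared (odds ratio 2.74, Fisher's exact adjusted p = 9.0e-10). The odds ratio was 1.91 for regions in ISC and not at E14.5 (Fisher's exact adjusted p = 1.1e-05) and 24.0 for the 57 at E14.5 and not at E12.5 (Fisher's exact adjusted p = 1.3e-10). Of the 57, 11 lay on X, 10 of them between 120113770 and 123303417. In the other 4 tests the Fisher's exact adjusted p was 0.441 to 1. With the 6136 strongest peaks per library the calls differed, on few X-linked regions. These sets differ in rank: of 735 regions listed at E14.5 and not in ISC, 720 had an ISC peak in its full lists. The call for E12.5 against E14.5 was lost, with 2 of 657 regions on X (odds ratio 7.28, Fisher's exact adjusted p = 0.159). One for regions listed at E14.5 and not in ISC was gained, with 9 of 735 (odds ratio 7.08, Fisher's exact adjusted p = 0.0021). The calls for ISC against enterocytes, with 12 of 776 (Fisher's exact adjusted p = 2.3e-07), for ISC against E14.5, with 11 of 1118 (Fisher's exact adjusted p = 0.0031), and for E14.5 against E12.5, with 10 of 428 (Fisher's exact adjusted p = 2.3e-07), were made in both. The E12.5 libraries had 0 Y regions each and the E14.5 libraries 15 and 19, and a difference in sex between these samples was not tested. The enterocyte libraries shared 1 input, which was not analysed here, and no explanation was tested.

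Regions called in both ISC libraries and no embryonic library were called in enterocytes less often than those ISC shared with E12.5. Of 5943 such regions, 52.8% had a peak in neither enterocyte library, against 16.8% of the 15309 shared with both E12.5 libraries. The short list of enterocyte replicate 1 does not account for this, since the odds ratio in replicate 2 alone was 5.61. Weaker peaks in ISC account for part: within 10 strata of ISC rank the odds ratio was 1.87 (1.74 to 2.02) in replicate 2, from 5.61, and 3.19 (2.92 to 3.50) in replicate 1, from 10.4. Neither this nor the shares of X-linked ISC regions and the clustering were repeated with equal numbers of peaks. A candidate explanation is H2A.Z particular to stem cells, but regions shared with E12.5 were selected for being called in more libraries, and that selection was not tested.

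Adult regions lay near one another: 15.6% had another adult region within 50 kb, against a mean of 6.91% and at most 10.6% in 1000 random draws from the same chromosomes. In draws matched on the local density of H2A.Z regions the mean was 11.1% and the highest 15.7%, above the observed 15.6% (permutation p = 0.0020). After regions within 5 kb were merged, 596 adult regions were left, in place of 810, and 8.39% had a neighbour. The random draws had a mean of 4.13%, and the highest equalled 8.39% (permutation p = 0.0020). The shares of 15.6% and 8.39% are thus of different sets of regions, so their difference does not measure merging alone. The bound set beforehand, a share above all 1000 draws, was met in neither test, so local density and pieces of broad regions were not excluded. In both tests the observed share still stood above the mean of the draws, so an average draw gave only part of the clustering. Other classes were not part of that hypothesis. The 3139 regions of both ISC libraries and no other stage had a neighbour of their kind in 32.2% of cases, against at most 26.7% in matched draws. For the 2010 regions of both E12.5 libraries and no other stage it was 19.5%. Matched draws gave at most 14.0% there, and draws from the same chromosomes 19.6%. Of the 87 embryonic regions 0% had one, where matched draws gave a mean of 0.287% (permutation p = 1).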
